A study of Mus musculus with 2 samples.

How the data were processed

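The series holds 2 libraries of dissociated L4-5 dorsal root ganglia from adult wild-type mice of the acetone-ether-water group, aged 8 weeks. Per the labels, tissue was digested with Liberase and papain at 37 °C and libraries were made with the 10x Genomics 3' v3.1 gel bead kit. The labels do not say that the replicates are separate animals, so the spread behind the p-values may be technical. Since library is a term of the fit, that spread is how far class differences varied between the 2 libraries, pooled over classes.

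The deposited matrices hold raw UMI counts per gene and cell barcode, written by Cell Ranger 5.0.1 on build mm10 per the file headers and the labels, after CASAVA 1.8. The deposited barcode and feature files hold values of another kind (unit other): cell barcodes, and Ensembl gene identifiers with symbols. The annotation release, the cell calling settings and the counting of intronic reads are not given in the sources used here. Gene positions were taken from GENCODE mouse release 21 on build GRCm38, which held 31184 of the 31253 gene identifiers.

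Barcodes with at least 500 genes and under 20% mitochondrial UMIs were kept, 8329 in replicate 1 and 11290 in replicate 2. Scrublet, as run in scanpy 1.11.5, set automatic thresholds that marked 5 and 0 cells, so the highest scores were removed at a rate of 0.8% per 1000 cells, 496 and 1013 cells. Cells were scaled to 10000 UMIs and log-transformed. From 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering with 10 iterations at resolution 1, and at 1.5 for neurons (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, seed 1). In all, 524 genes of the fixed lists, which held no markers, and all mitochondrial and ribosomal protein genes were kept out of clustering, and 3393 genes were used for it at either step. Figures were drawn with matplotlib 3.10.9.

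Clusters were named from fixed markers by the class with the highest mean score. A name needed 3 markers detected in at least 10% of cells at 1.5 times the level elsewhere. A cluster stayed unnamed where its 10 leading genes held more markers of another class of the same round (broad or neuron) than of its own. A neuron cluster also stayed unnamed where they held at least 2 markers of non-neuronal classes, counted together, and more of them than of its own. Any cluster stayed unnamed where its median depth was under 1/3 of the library median and no marker led. The depth, non-neuronal and leading-gene conditions were refined after the data were examined. Gene lists, comparisons, and the tests and thresholds of the comparisons were fixed before the data were examined, while some tests of technical explanations were chosen after the results they weigh were seen.

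UMIs were summed per class and library for classes with at least 20 cells in each. Differences were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, its filter on low counts, and the quasi-likelihood test with class and library as terms and Benjamini-Hochberg adjustment at 0.05. The neuron fit held 8 classes, 16 sums, 13056 genes and 7 residual degrees of freedom, with a common biological coefficient of variation of 0.123. The broad fit held 13 classes, 26 sums, 13509 genes and 12 degrees of freedom, with a coefficient of 0.149. For a side with a pair of classes, folds average the logs of the classes, while CPM averages their levels. Tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 96% and 100%, with 10 false calls among 206 of 12200 genes. The changed genes were drawn from those at 10 CPM or more, and classes were otherwise given the same profile. No library effect and no clustering were simulated, so these rates need not hold for the real comparisons.

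Lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, with adjustment over lists and contrasts. The lists were itch receptors, itch signal transduction, pain and nociceptor genes, sodium, potassium, calcium and TRP channels, purinergic, glutamate, GABA and glycine, and acetylcholine receptors, neuropeptides and granins, axon injury and regeneration, immediate early genes, heat shock, interferon response, itch and pain mediators, oxidative phosphorylation, cholesterol synthesis and MHC class II. Genes on more than 1 list count in each. Genes to be named were, per comparison, the 10 with the largest fold in each direction among those passing, not used to cluster, alike in sign in both libraries and at 20 CPM or more on the higher side in both. List members at 10 CPM or more were counted, with up to 4 examples a direction. A fold against 0 counts uses a floor of 3 counts over the class, and ratios with 1 to 3 counts carry an exact 95% counting interval.

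Shares carry exact Clopper-Pearson 95% intervals, and receptor shares were taken after thinning each cell to 2000 UMIs, leaving out cells below that. Alternatives were lower and higher cluster resolution (0.6 and 0.8, 1.5 and 2.5), a stricter filter (1000 genes, 10% mitochondrial), doublets kept, libraries centred, count splitting, RLE factors, DESeq2 1.42.0, no filter on low counts, no library term, at least 50 cells per class, a fold of at least 1.5, thinning to 1000 or 5000 UMIs or none, and each replicate left out. Neurons of at least 10000 UMIs, another clustering seed and thinning to 20000 UMIs were added after the data were examined. With 2 samples in 1 group, outliers among samples and differences between groups could not be tested, and reads were not analysed here. Some genes that meet the rules for naming are not reported here.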

Results

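Dorsal root ganglia of lumbar levels L4-5 from adult wild-type mice were profiled by droplet-based single-cell RNA sequencing. All mice belonged to the acetone-ether-water (AEW) group, a model in which solvents and water dry the skin and the mice scratch. The group held 2 libraries, called replicates 1 and 2. The labels name no untreated or pain group, so AEW could not be compared with another state, and every comparison was made between cell classes within the libraries. Replicate 1 held 113251556 UMIs in 8818 barcodes, and replicate 2 held 102347251 UMIs in 11767 barcodes. After filtering, 7833 and 10277 cells remained, with medians of 4982 and 4102 UMIs and of 2059 and 1888 genes per cell.

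The first question was which cells the ganglia gave. Class names stand for clusters like that cell type by their markers. Satellite glia, which wrap the cell bodies of sensory neurons, were the largest class at 32.6% ± 2.91 of kept cells (SD, n = 2 libraries). Neurons made up 10.6% ± 2.58, with 691 cells in replicate 1 and 1281 in replicate 2, although the labels give neuron as the cell type. Myelinating Schwann cells, which insulate large axons, made up 9.97% ± 5.27, endothelial cells 6.08% ± 1.86, non-myelinating Schwann cells 5.75% ± 0.847, fibroblasts 4.62% ± 1.27 (with a cluster of 249 cells that scored 2.39 for fibroblasts and 2.37 for perineurial cells, with no marker leading) and mural cells of the vessel wall 3.94% ± 0.068. Immune cells were macrophages at 3.62% ± 0.184, a T or NK cluster at 1.09% ± 0.424, neutrophils at 0.880% ± 0.035 and B cells at 0.763% ± 0.104. Erythroid cells made up 1.67% ± 0.893 and cycling cells 0.510% ± 0.199. The T or NK cluster was also led by Ly6c2, Plac8 and Cd209a, genes of myeloid cells, and held macrophage markers at 2485 and 2415 CPM (UMIs of the genes scaled to a common library total). The cycling cluster held erythroid markers at 106348 and 162032 CPM. The remaining 17.9% ± 2.18 of barcodes could not be named, and their median depth was 1015 UMIs in replicate 1 and 1221 in replicate 2. Myelinating Schwann cells differed most between the libraries among the classes above 5%, with 13.7% in replicate 1 (exact Clopper-Pearson 95% interval 12.9 to 14.5) and 6.25% in replicate 2 (5.79 to 6.73).

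Of the neurons, 588 in replicate 1 and 725 in replicate 2 fell into 8 classes, each named for the neuron type its markers resemble, so that each class name stands for a type-like cluster. The NP1 class, non-peptidergic nociceptors that carry the receptor Mrgprd, was the largest at 30.2% ± 2.08 of named neurons (SD, n = 2 libraries). Peptidergic C-fibre nociceptors (PEP-C) made up 24.3% ± 2.88, and peptidergic A-delta nociceptors (PEP-A) 4.98% ± 0.412 (7.67% with libraries centred). NP1 included a shallow cluster of 50 and 57 cells, with median depths of 5816.5 and 2123 UMIs. Without that cluster NP1 would be smaller than PEP-C in replicate 2. The TH class, low-threshold C-fibre touch receptors, made up 13.0% ± 5.41. The classes tied to itch were NP2, with the chloroquine receptor Mrgpra3, at 8.06% ± 0.866 (5.17% at low cluster resolution), and NP3, with the peptides Nppb and Sst, at 4.94% ± 0.945. Cold-sensing TRPM8 neurons made up 7.31% ± 0.971 and large A-fibre neurons (NF) 7.23% ± 3.01. The TRPM8 class included a cluster of 33 cells led by Penk, Calb1 and Rxfp1, with no marker of the class among its 10 leading genes and Trpm8 at 3.0 and 0 CPM, against 202.4 and 27.1 in the other cluster, so its name is weakly held. TH neurons took 9.18% of named neurons in replicate 1 (95% interval 6.97 to 11.8) and 16.8% in replicate 2 (14.2 to 19.8), a difference beyond counting error among named neurons only. Another 103 neurons of 691 and 556 of 1281 were left unnamed, an unequal loss. Of all neurons, TH held 54 of 691 and 122 of 1281. Among the unnamed, cluster 22 (5 and 58 cells) and cluster 27 (0 and 33) scored highest for TH, with 6 markers detected in each. The naming thus left out TH-like cells mostly of replicate 2, and the difference is not shown to come from it. Median depth of the named classes ran from 49792 UMIs in NF to 139679.5 in NP1 in replicate 1, and from 41791 in TRPM8 to 69724 in NP1 in replicate 2.

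**Figure D1:**
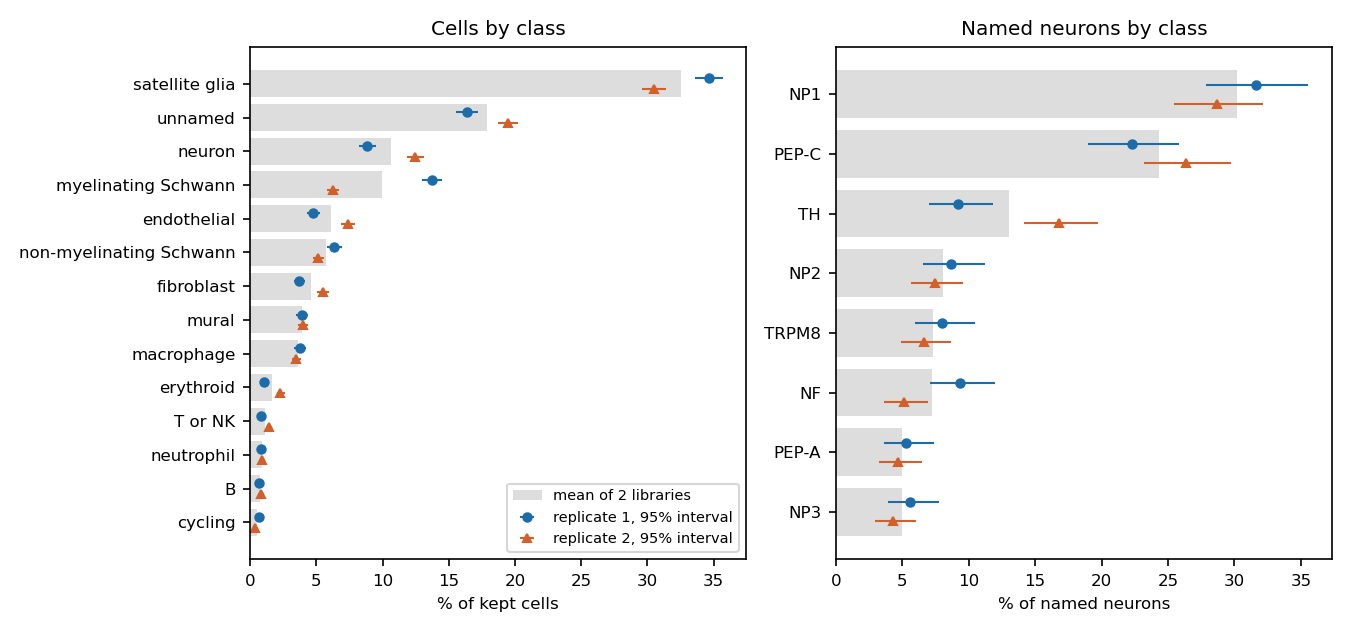
Shares of broad cell classes (% of kept cells) and of neuron classes (% of named neurons). Bars are means of 2 libraries and points are single libraries with exact 95% intervals. Satellite glia were the largest broad class at 32.6%. NP1 was the largest neuron class at 30.2%, with its shallow cluster counted.

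The title of the series sets itch against pain, so the itch-associated classes NP2 and NP3 were compared with the peptidergic nociceptor classes PEP-C and PEP-A. The receptors for leukotrienes and for the itch cytokine interleukin 31 were far higher in the itch-associated classes. Cysltr2, the type 2 cysteinyl leukotriene receptor, was higher by 5.51 ± 0.25 on the log2 scale (SE, n = 2 libraries, adjusted p = 3.25e-11), at 167 ± 24.9 CPM against 1.53 ± 0.209 (SD). Il31ra and Osmr, which together form the interleukin 31 receptor, were higher by 4.74 ± 0.46 (adjusted p = 4.91e-07) and 4.18 ± 0.21 (adjusted p = 1.41e-10). The Il31ra difference came almost wholly from NP3, at 382 CPM against 2.52 in NP2, and Cysltr2 was also far higher in NP3 than in NP2. Jak1, the kinase that such cytokine receptors signal through, was higher by 3.13 ± 0.11 (adjusted p = 3.93e-12) and reached 2011 ± 26.5 CPM against 160 ± 2.02. The peptidergic classes were instead higher in the acid-sensing channel Asic3, in the neuropeptide precursor Cartpt and in the calcium channel gene Cacna1e.

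Among genes not used for clustering and at 20 CPM or more on the higher side, A3galt2, a glycosyltransferase (log2 4.93 ± 0.30), P2rx2, an ATP-gated channel (4.60 ± 0.37), and Mindy4b-ps (4.35 ± 0.23) were also higher in NP2 and NP3. Mei1 (3.66 ± 0.21), Smim5 (3.29 ± 0.14) and the sodium-calcium exchanger Slc8a1 (3.17 ± 0.19) were higher by less. In the other direction, the transcription factor Bcl11a had 2 UMIs in NP2 and NP3 against 942, a ratio of 231 with a counting interval of 63.7 to 1909. The R-type calcium channel gene Cacna1e had 3 UMIs against 1072, a ratio of 175 with an interval of 59.8 to 851. The vesicle GTPase Rab3b (−6.88 ± 0.45), the complement protease Masp1 (−5.85 ± 0.54), Asic3 (−5.79 ± 0.36), the potassium channel subunit Kcnmb2 (−5.54 ± 0.46), the scaffold Mpp2 (−5.45 ± 0.42), Cartpt (−5.33 ± 0.50), the sulfatase Sulf1 (−5.25 ± 0.27) and Plekha2 (−5.16 ± 0.33) were also lower. Asic3 was at log2 −4.49 in replicate 1 and −6.35 in replicate 2. Masp1 stood at 3.25 CPM against 24.8, a smaller difference than its fold, which averages logs over classes.

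The gene groups fixed in advance went different ways. Of 13 itch receptors with at least 10 CPM on either side, 7 were higher in NP2 and NP3, 2 lower and 4 not called. The histamine receptors Hrh1 (4.42 ± 0.39) and Hrh2 (3.38 ± 0.34) were higher, and the neuropeptide Y receptor Npy1r (−5.13 ± 0.51) and the sphingosine phosphate receptor S1pr3 (−3.04 ± 0.17) lower. Il4ra (−0.06, adjusted p = 0.829) and Htr2a (−0.44, adjusted p = 0.318) did not pass. Of 13 genes of itch signal transduction, 9 were higher and 1 lower, with Plcb3 at 1.82 ± 0.11, Gnaq at 1.02 ± 0.13 and Plcb1 at −3.43 ± 0.22. Trpv1, the capsaicin receptor, was called higher by 1.02 ± 0.19, but its mean CPM was alike, 177 ± 42.0 against 171 ± 50.4, because the fold averages logs over classes and PEP-A held 23.3 ± 3.25 against 319 ± 104.1 in PEP-C. Of 30 pain and nociceptor genes, 8 were higher and 16 lower in NP2 and NP3. The nociceptor sodium channel Scn11a (1.47 ± 0.10) and the ATP-gated channel P2rx3 (1.36 ± 0.19) were higher, while Cacna1h (−4.53 ± 0.46) and Asic1 (−4.09 ± 0.66) were lower. The prokineticin receptor Prokr2 had 2 UMIs in NP2 and NP3 against 425, a ratio of 104 with an interval of 28.7 to 863. Scn9a, the sodium channel whose human loss abolishes pain, did not pass (0.22, adjusted p = 0.0786).

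As whole lists, itch signal transduction was higher in NP2 and NP3 (17 genes tested, 9 higher and 2 lower, 12 adjusted over the list alone; adjusted p = 7.49e-04, and adjusted p = 0.0897 with an estimated correlation). Itch receptors did not pass (24 tested, 9 higher and 7 lower, 17 adjusted over the list alone; adjusted p = 0.0562, and their median of −0.12 and mean of 0.05 differed in sign). Pain and nociceptor genes were lower (32 tested, 9 higher and 17 lower, 28 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.0986 with an estimated correlation). Potassium channels were lower, with 14 of 72 higher and 32 lower, 46 called when adjusted over the list alone (adjusted p = 7.06e-04, and adjusted p = 0.224 with an estimated correlation). Calcium channels were lower with 3 of 19 higher and 10 lower, 15 adjusted over the list alone (adjusted p = 0.0352, and adjusted p = 0.289 with an estimated correlation). Receptors for fast transmitters were lower too. Glutamate receptors had 0 of 18 higher and 9 lower, 9 adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.202 with an estimated correlation), and GABA and glycine receptors 0 of 14 higher and 8 lower, 9 adjusted over the list alone (adjusted p = 0.00984, and adjusted p = 0.289 with an estimated correlation). Acetylcholine receptors had 1 of 7 higher and 4 lower, 6 adjusted over the list alone (adjusted p = 0.0315, and adjusted p = 0.202 with an estimated correlation). Sodium channels (3 of 12 higher, 6 lower, 10 adjusted over the list alone; adjusted p = 0.274), TRP channels (7 of 14 higher, 3 lower, 10 adjusted over the list alone; adjusted p = 0.0504) and neuropeptides and granins (2 of 15 higher, 8 lower, 11 adjusted over the list alone; adjusted p = 0.0562) did not pass.

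In all, 4903 of 13056 genes passed at an adjusted p under 0.05, 2239 higher and 2664 lower in NP2 and NP3, and 3636 of them were not used for clustering. With a fold of at least 1.5 required, 2249 passed. Classes were defined from the same counts, and a pair of classes stood on each side, so a fold can describe a single class. With PEP-A and NP3 left out for having under 50 cells, Trpv1 and Il13ra1 turned to −1.29 and −1.19. Of the other transduction genes called higher, Stat3 and Lifr turned to −0.36 and −0.29. The lists were not tested at that setting. On build GRCm38, Cysltr2 (ENSMUSG00000033470) lies on chromosome 14 from 73025603 to 73049114, and Il31ra (ENSMUSG00000050377) on chromosome 13 from 112519898 to 112594360. Osmr (ENSMUSG00000022146) lies on chromosome 15 from 6813577 to 6874969, Jak1 (ENSMUSG00000028530) on chromosome 4 from 101152367 to 101265282, and Asic3 (ENSMUSG00000038276) on chromosome 5 from 24413392 to 24417835. Bcl11a (ENSMUSG00000000861) lies on chromosome 11 from 24078056 to 24174123 and Cacna1e (ENSMUSG00000004110) on chromosome 1 from 154390731 to 154884501.

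**Figure D2:**
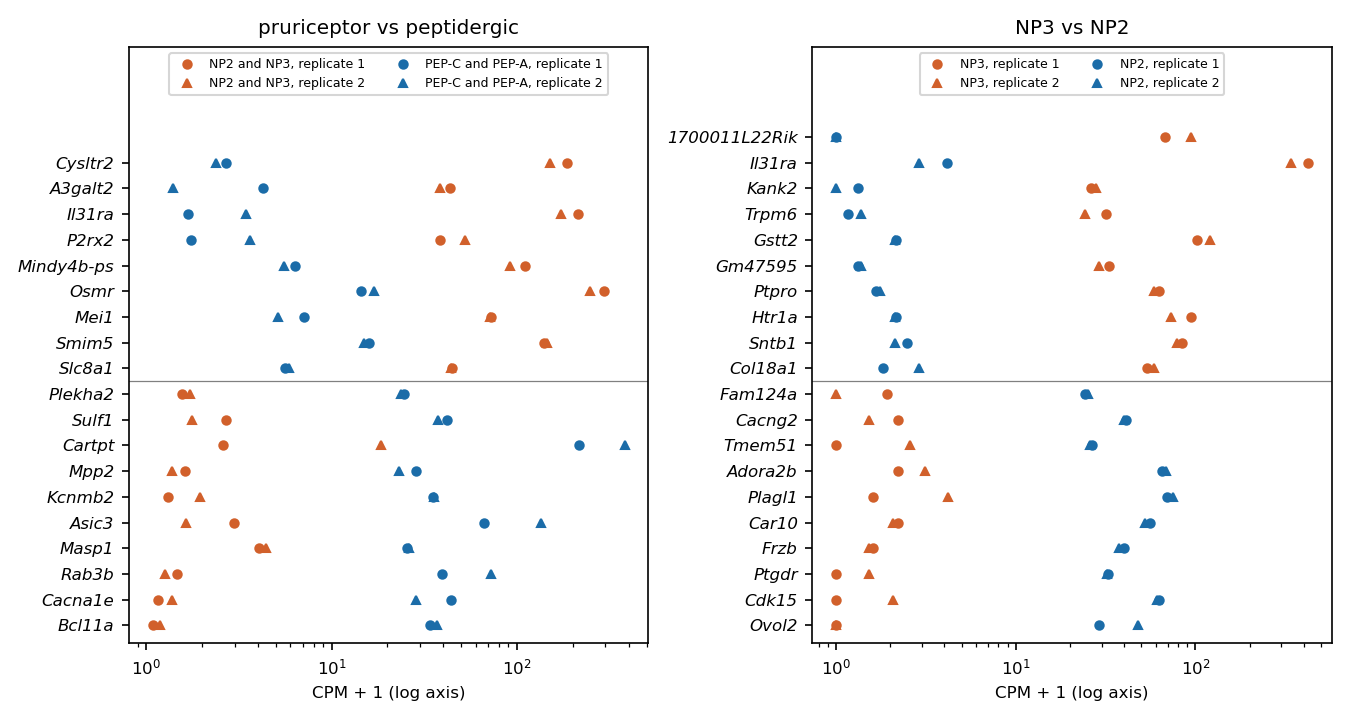
Levels of named genes in each of 2 comparisons, as CPM + 1 on a log axis, with 1 point per library and side. As means of NP2 and NP3, Cysltr2 and Il31ra stood at 167 and 192 CPM against 1.53 and 1.56 in the peptidergic classes. Il31ra was almost only in NP3, and Cysltr2 was far higher in NP3 than in NP2.

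The itch-associated classes were next compared with each other. Il31ra was nearly confined to NP3 among these, at 382 ± 59.6 CPM (SD, n = 2 libraries) against 2.52 ± 0.874 in NP2, a log2 difference of 6.97 ± 0.38 (adjusted p = 2.13e-09). Cysltr2 (5.04 ± 0.24), the serotonin receptor Htr2a (5.20 ± 0.44), the protease receptor F2rl1 (4.38 ± 0.55) and Osmr (2.39 ± 0.24) were also higher in NP3. Jak1 reached 3526 ± 20.6 CPM in NP3 against 496 ± 32.3 in NP2 (2.66 ± 0.15, adjusted p = 1.33e-09). NP2 neurons were higher in the prostaglandin D2 receptor Ptgdr, the calcitonin-related peptide gene Calcb and the transcription factor Ovol2.

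Among genes not used for clustering, 1700011L22Rik had 395 UMIs in NP3 and 0 in NP2, at least 222-fold higher against a floor of 3 counts over the class. Ptpro, a receptor phosphatase (6.24 ± 0.33), Gstt2, a glutathione transferase (6.39 ± 0.31), the serotonin receptor Htr1a (6.03 ± 0.31), the syntrophin Sntb1 (5.77 ± 0.38) and the collagen Col18a1 (5.38 ± 0.49) were higher in NP3. Other genes had 2 or 3 UMIs in NP2, the magnesium channel Trpm6 (ratio 122, counting interval 33.2 to 1018), Kank2 (113, 30.6 to 942) and the antisense transcript Gm47595 (88.7, 29.8 to 435). Lower in NP3, Ovol2 (ENSMUSG00000037279, chromosome 2, 144305175 to 144332146) had 0 UMIs against 294, at least 58.2-fold lower against the same floor. Ptgdr had 1 UMI in NP3 (ratio 162, interval 28.8 to 6424), Cdk15 had 2 (158, 43.5 to 1307) and the secreted Wnt antagonist Frzb had 3 (65.7, 22.3 to 320.2). Tmem51 and Fam124a had 3 UMIs each, with ratios of 43.5 (14.7 to 213) and 40.8 (13.8 to 199). Car10 (−5.65 ± 0.35), Plagl1 (−5.64 ± 0.39), the adenosine receptor Adora2b (−5.57 ± 0.47) and Cacng2, a partner of AMPA receptors (−5.53 ± 0.51), were also lower.

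Of 13 itch receptors above 10 CPM, 9 were higher in NP3 and 4 lower, the latter Ptgdr, Hrh1 (−1.37 ± 0.38), Il4ra (−0.95 ± 0.25) and Crlf2 (−0.74 ± 0.21). As a list, itch receptors were higher (24 tested, 10 higher and 6 lower, 18 adjusted over the list alone; adjusted p = 1.33e-04, and adjusted p = 0.0580 with an estimated correlation). Of 12 genes of itch signal transduction, 4 were higher, Jak1, Lifr (0.89 ± 0.17), Trpv1 (0.86 ± 0.25) and Stat3 (0.81 ± 0.13), and 1 was lower, but the list did not pass (adjusted p = 0.164). Of 24 pain and nociceptor genes, 7 were higher, such as P2rx2 (2.25 ± 0.35) and the transcription factor Runx1 (216 against 56.2 CPM). The 5 lower included Kcnq3 (−4.67 ± 0.59) and Calcb (−4.52 ± 0.35), and the list did not pass (adjusted p = 0.834). Potassium channels were lower in NP3, with 14 of 72 higher and 23 lower, 39 adjusted over the list alone (adjusted p = 0.0432, and adjusted p = 0.414 with an estimated correlation), as were neuropeptides and granins, with 2 of 15 higher and 8 lower, 11 adjusted over the list alone (adjusted p = 0.0432, and adjusted p = 0.408 with an estimated correlation). Immediate early genes were higher, with 9 of 17 higher and 0 lower, 9 adjusted over the list alone (adjusted p = 7.49e-04, and adjusted p = 0.317 with an estimated correlation). In total 3428 of 13056 genes passed, 1644 higher and 1784 lower in NP3, of which 2524 were not used for clustering, and 1546 passed at a fold of at least 1.5. NP3 held 33 and 31 cells, and satellite glia markers stood at 2477 and 1207 CPM in it against 1108 and 784 in NP2.

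NP1 neurons were then compared with the mean of NP2 and NP3, to set the Mrgprd nociceptors beside the itch-associated classes. NP1 was higher in Grik1, a kainate-type glutamate receptor, by 5.37 ± 0.42 on the log2 scale (SE, n = 2 libraries, adjusted p = 3.67e-08), at 622 ± 3.13 CPM against 37.7 ± 17.7. Kcnab1, a potassium channel subunit (ENSMUSG00000027827, chromosome 3, 65109384 to 65378223), was higher by 5.79 ± 0.26 (adjusted p = 1.32e-10). The itch cytokine receptors and Jak1 were low in NP1, with Il31ra at 1.01 ± 0.317 CPM, Osmr at 9.11 ± 1.12 and Jak1 at 109 ± 5.05. Trpv1 was also lower in NP1 (−3.14 ± 0.25), at 16.9 ± 6.02 CPM against 177 ± 42.0, and the irritant receptor Trpa1 higher (1.69 ± 0.24), at 57.6 ± 4.42 against 19.9 ± 0.080.

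Among genes not used for clustering and at 20 CPM or more on the higher side, those higher in NP1 included the sialyltransferase St6galnac5 (6.44 ± 0.48; ENSMUSG00000039037, chromosome 3, 152817081 to 152982246), the methyltransferase Prmt8 (6.06 ± 0.29), Kcnab1, Grik1 and the homeobox gene Hoxb5 (5.29 ± 0.26). Gm16364 (4.54 ± 0.27), Ptgdr (4.46 ± 0.50), the potassium channel Kcnc4 (4.30 ± 0.41) and the phosphodiesterase Pde11a (4.21 ± 0.36) were higher as well. Ptgdr stood at 50.5 ± 4.59 CPM in NP1 against 15.8 in the itch-associated classes, a smaller difference than its fold, which averages logs over classes. Ptgdr was also called higher in NP2 than in NP3, so its level of 15.8 CPM came from NP2. Lower in NP1 were Slc8a1 (−6.50 ± 0.31; ENSMUSG00000054640, chromosome 17, 81373105 to 81738377), P2rx2 (−5.67 ± 0.44), the calpain Capn9 (−5.12 ± 0.25) and Il31ra (−4.88 ± 0.47). 1700001L19Rik (−4.85 ± 0.33), Sectm1b (−4.68 ± 0.64), the actin-bundling protein gene Fscn1 (−4.63 ± 0.25), Lrrc20 (−4.53 ± 0.26) and Htr1a (−4.23 ± 0.43) were lower as well.

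Of 13 itch receptors, 3 were higher in NP1 and 8 lower. The prostaglandin E2 receptor Ptger3 was higher by 7.25 ± 0.48, at 14.0 ± 2.78 CPM against 0.313 ± 0.093, and Hrh1 (−6.37 ± 0.51) and Hrh2 (−4.43 ± 0.41) were lower. Htr2a was called higher (1.96 ± 0.29) at like CPM, 15.1 against 14.4, and stood at −0.14 in replicate 1 and 0.29 in replicate 2 when taken from CPM by library. The itch receptor list was lower in NP1 (24 tested, 4 higher and 12 lower, 16 adjusted over the list alone; adjusted p = 7.20e-05, and adjusted p = 0.0653 with an estimated correlation). Of 12 transduction genes 4 were higher and 3 lower, and the list did not pass (adjusted p = 0.437), with a median of 0.10 although its test pointed down. Of 23 pain and nociceptor genes, 7 were higher, among them Calcb (3.02 ± 0.25) and the touch channel Piezo2 (2.11 ± 0.19). The 6 lower included Ptgir (−3.68 ± 0.37) and Kcnq3 (−3.04 ± 0.75), and the list did not pass (adjusted p = 0.554, with a median of 0.20 and a mean of −0.10). Potassium channels were higher in NP1, with 25 of 72 higher and 10 lower, 37 adjusted over the list alone (adjusted p = 3.53e-04, and adjusted p = 0.195 with an estimated correlation). Immediate early genes were lower, with 1 of 17 higher and 10 lower, 13 adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.414 with an estimated correlation). In total 3684 genes passed, 2057 higher and 1627 lower in NP1, of which 2727 were not used for clustering, and 1569 passed at a fold of at least 1.5.

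Neurons were compared with satellite glia to show which of these cells carry the receptors. Nociceptor channels stood far higher in neurons, with Trpv1 at 122 ± 12.1 CPM against 6.00 ± 0.633 (log2 4.23 ± 0.23, SE, n = 2 libraries, adjusted p = 2.87e-13), and Scn11a (4.07 ± 0.35), Cacna1b (4.06 ± 0.21) and Scn10a (3.85 ± 0.25) higher as well. Satellite glia were higher in the endothelin receptor Ednrb, at 1184 ± 5.54 CPM against 9.81 ± 1.29 (−7.02 ± 0.51, adjusted p = 3.18e-11; ENSMUSG00000022122, chromosome 14, 103814625 to 103844402), in the gap junction gene Gja1, at 169 ± 8.94 CPM against 1.39 ± 0.276 and in the transcription factor Sox2 (−6.86 ± 0.39). The enkephalin precursor Penk was higher in neurons by 5.52 ± 0.37 (adjusted p = 6.13e-11; ENSMUSG00000045573, chromosome 4, 4133531 to 4138819).

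Other neuronal genes not used for clustering were the potassium channels Kcnc2 (4.69 ± 0.38) and Kcng2 (4.58 ± 0.40), Mindy4b-ps (4.67 ± 0.46), Ldb2 (4.53 ± 0.31), the chromatin remodelling subunit Actl6b (4.53 ± 0.24), the vesicle protein gene Syt5 (4.49 ± 0.22), Serinc2 (4.46 ± 0.35), F2rl2 (4.45 ± 0.26) and Plcxd3 (4.44 ± 0.32). On the glial side were Pde7b (−7.09 ± 0.44), Cxcl10 (−6.96 ± 0.91), Sema3g (−6.95 ± 0.31), the aspartoacylase gene Aspa (−6.87 ± 0.34), Smco3 (−6.87 ± 0.38), Lbhd2 (−6.84 ± 0.39) and Car13 (−6.75 ± 0.29). The chemokine Cxcl10 stood at 134 CPM in satellite glia of replicate 1 and at 675 in those of replicate 2. Of 11 itch receptors, 7 were higher in neurons, such as Il31ra (4.98 ± 0.51) and Npy1r (4.21 ± 0.46). The 4 higher in glia were Ednrb, the double-stranded RNA sensor Tlr3 (−5.05 ± 0.33), S1pr1 (−2.46 ± 0.28) and S1pr3 (−2.02 ± 0.23). The itch receptor list did not pass (21 tested, 11 higher and 5 lower, 16 adjusted over the list alone; adjusted p = 0.318). Of 13 transduction genes above 10 CPM, 10 were higher and 1 lower, Jak2 (−0.88 ± 0.21).

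Pain and nociceptor genes were higher in neurons as a list (29 tested, 26 higher and 1 lower, 27 adjusted over the list alone; adjusted p = 7.16e-08, and adjusted p = 0.0592 with an estimated correlation). Neuropeptides and granins had 13 of 13 higher, 13 adjusted over the list alone (adjusted p = 1.91e-05, and adjusted p = 0.0979 with an estimated correlation). Calcium channels had 16 of 18 higher and 1 lower, 17 adjusted over the list alone (adjusted p = 7.86e-05, and adjusted p = 0.0580 with an estimated correlation). Potassium channels had 41 of 60 higher and 12 lower, 53 adjusted over the list alone (adjusted p = 2.38e-04, and adjusted p = 0.110 with an estimated correlation), and sodium channels 10 of 11 higher, 10 adjusted over the list alone (adjusted p = 7.06e-04, and adjusted p = 0.0986 with an estimated correlation). GABA and glycine receptors had 8 of 9 higher, 8 adjusted over the list alone (adjusted p = 8.24e-04, and adjusted p = 0.0584 with an estimated correlation). Immediate early genes were lower in neurons, with 0 of 16 higher and 12 lower, 13 adjusted over the list alone (adjusted p = 0.0271, and adjusted p = 0.681 with an estimated correlation). The glia they were set against included a cluster led by Myc and Egr3 (57 cells of replicate 1 and 828 of replicate 2). The name of that cluster is weakly held, since it scored 1.16 for satellite glia with no marker among its 10 leading genes. Another cluster was led by Cxcl10 (20 and 811). Fos stood at 7004 and 5887 CPM in these clusters in replicate 2, against 1091 in other satellite glia of that library. In total 8910 of 13509 genes passed, 4508 higher and 4402 lower in neurons, of which 6971 were not used for clustering. The balance moved with the scaling, to 3702 higher and 5235 lower with RLE factors and 4044 higher and 5691 lower with DESeq2, where the median log2 difference of all genes was −0.22 and −0.11. Satellite glia held 17.4 ± 11.2 CPM of Scn11a and 21.7 ± 8.91 of Scn10a, so folds toward neurons read against a background whose source was not tested.

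Shares of single neurons with a receptor were measured after thinning every cell to 2000 UMIs, with satellite glia thinned alike as the background. Median depths before thinning were 104801 and 61414 UMIs in NP3 and 7548 and 6009.5 in satellite glia. In NP3, Osmr was found in 57.8% ± 0.346 of neurons (SD, n = 2 libraries; 1.65% of satellite glia), Il31ra in 55.1% ± 17.9 (0.190%) and Cysltr2 in 39.1% ± 0.484 (0.150%). Il31ra was found in 42.4% of the 33 NP3 neurons of replicate 1 and in 67.7% of the 31 of replicate 2. In NP2, with median depths of 133387 and 48205 UMIs, Il31ra was found in 0 of 43 and 0 of 47 neurons, which allows shares with a UMI at this depth of up to 6.98% and 6.38% by 3 counts (exact upper limits 8.22% and 7.55%) and does not limit the cells that express it. Osmr was found there in 11.1% ± 0.700, Il4ra in 8.91% ± 0.560 (satellite glia 0.736%) and Hrh1 in 6.58% ± 2.73 (0.016%). F2rl1 was found in 1 NP3 neuron of each library, 3.13% on average.

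Trpv1 was found in 46.3% ± 5.27 of TRPM8 neurons, 42.4% ± 8.50 of NP3 and 42.3% ± 13.0 of PEP-C (satellite glia 1.31%). In the TRPM8 class Trpv1 stood at 1449.4 and 1269.4 CPM in the cluster of 33 cells almost without Trpm8 and at 106.7 and 91.4 in the other, so the class share mixes unlike clusters. In NP2 the Trpv1 share was 20.9% in replicate 1 and 8.51% in replicate 2, and in NP1 it was 3.34% ± 0.838. Trpa1 was found in 13.0% ± 1.76 of NP1 and 11.0% ± 2.70 of NP3 neurons (satellite glia 0.452%). Piezo2 was found in 81.7% ± 0.343 of TH, 62.9% ± 6.64 of NF, 50.4% ± 11.9 of PEP-A and 36.3% ± 5.32 of NP1 neurons (satellite glia 5.35%). Trpv1 was found in no TH neuron, which allows shares with a UMI at this depth of up to 5.56% and 2.46% by 3 counts (exact upper limits 6.60% and 2.98%). P2rx3 was found in 12.9% of NP1 neurons in replicate 1 and 4.40% in replicate 2 (satellite glia 0.434%). The serotonin receptor Htr7 was found in 5.43% ± 0.035 of NF neurons (0.260%). Scn10a in TRPM8 neurons, at 2.11%, was below the 5.00% of satellite glia and was not told apart from background. Thinning matched UMIs and not the share of RNA from other cells, so the comparison does not settle whether it was background. Lifr was found in 23.9% of satellite glia. Oprm1, the mu opioid receptor, was found on average in at most 3.17% of any neuron class.

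An itch receptor together with Trpv1 or Trpa1 was found in 37.6% ± 6.08 of NP3 neurons (SD, n = 2 libraries), 11.3% of NP2 and 7.22% ± 0.114 of NP1, against 0.134% of satellite glia. Itch receptors here were Hrh1, Il31ra, Osmr, Cysltr2, Htr7, F2rl1, Il4ra, Mrgpra3, Mrgprx1 and Mrgprd. Mrgprd is a naming marker of NP1, and Mrgpra3 and Mrgprx1 are naming markers of NP2. The receptor part of the NP1 and NP2 shares was thus partly set by the naming. For NP2 replicate 1 gave 16.3%. These shares depend on depth, and the NP3 share was 14.0% at 1000 UMIs and 82.4% at 5000, so they compare classes at a matched depth and do not count expressing cells. In replicate 2 NP2, at 6.38%, was below NP1, at 7.14%. No test was made between classes, and counting intervals cover counting error alone.

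**Figure D3:**
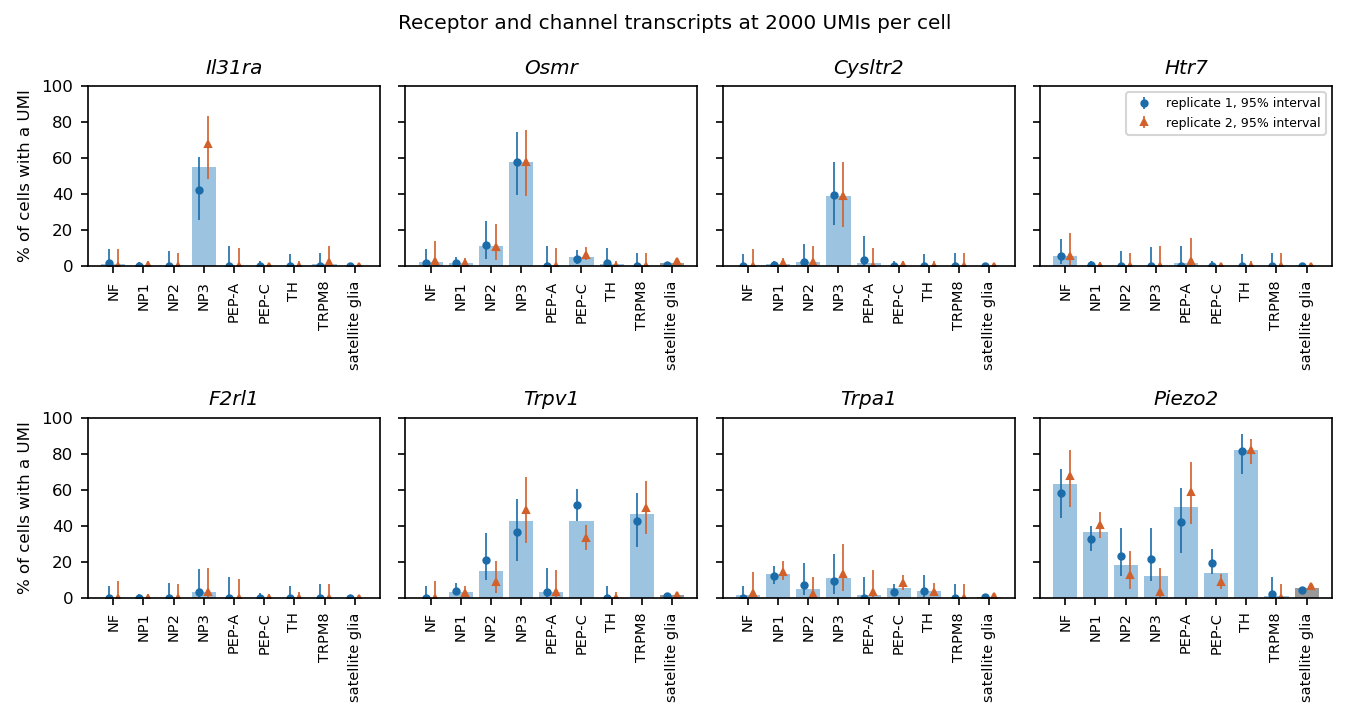
Share of neurons (%) with at least 1 UMI of each of 8 receptors after thinning to 2000 UMIs, by neuron class. Bars are means of 2 libraries, points are single libraries with 95% intervals and satellite glia are the grey background; Il31ra reached 55.1% in NP3 and 0 in NP2.

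Genes of axon injury and regeneration and of recent activity were compared between each neuron class and the mean of the others. PEP-C neurons stood out, with 15 of 17 injury genes higher and 0 lower, 15 adjusted over the list alone (adjusted p = 7.98e-15, and adjusted p = 0.00657 with an estimated correlation). Gap43, a growth cone protein gene, was higher in PEP-C by 2.56 ± 0.11 on the log2 scale (SE, n = 2 libraries), at 1342 and 1166 CPM against 461 and 456 in the other classes. The chemokine Ccl2 was higher by 3.61 ± 0.25, at 64.7 and 245 CPM against 7.03 and 29.0, and Stmn4 by 2.87 ± 0.17, at 97.5 and 82.9 against 25.8 and 27.1. The transcription factors Klf6 (1.72 ± 0.09), Jun (1.53 ± 0.15), Atf3 (1.26 ± 0.20) and Sox11 (1.06 ± 0.20) were also higher, as was Cacna2d1, the gabapentin target (1.53 ± 0.10). Sprr1a was called at 2.48 ± 0.90 (adjusted p = 0.0479) from 0.278 and 3.997 CPM against 3.45 and 1.54, so its direction differed between libraries. Of immediate early genes, 14 of 17 were higher in PEP-C and 0 lower, 16 adjusted over the list alone, with Btg2 at 2.54 ± 0.20 and Fos at 1.04 ± 0.16 (adjusted p = 2.07e-04, and adjusted p = 0.272 with an estimated correlation). Heat shock genes did not pass, with 1 of 9 higher and 2 lower, 3 adjusted over the list alone (adjusted p = 0.762; their median was 0.09 while the test pointed down).

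PEP-A neurons had 9 of 17 injury genes higher and 2 lower, 11 adjusted over the list alone, with Gap43 at 2.99 ± 0.11 and the macrophage growth factor Csf1 at 2.29 (adjusted p = 0.00110, and adjusted p = 0.0670 with an estimated correlation). TH neurons went the other way, with 1 of 17 injury genes higher and 11 lower, 12 adjusted over the list alone, and Gap43 at −4.31 ± 0.20 (adjusted p = 5.01e-05, and adjusted p = 0.0584 with an estimated correlation). Immediate early genes were lower in TH, with 0 of 17 higher and 12 lower, 12 adjusted over the list alone (adjusted p = 0.00209, and adjusted p = 0.345 with an estimated correlation), and in NP1, with 1 higher and 11 lower, 13 adjusted over the list alone (adjusted p = 0.0432, and adjusted p = 0.485 with an estimated correlation). They were higher in NP3, with 8 of 17 higher and 1 lower, 10 adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.428 with an estimated correlation). In TRPM8 neurons 10 were higher and 2 lower, 12 adjusted over the list alone, with Fos at 1.65 ± 0.16 (adjusted p = 0.0153, and adjusted p = 0.421 with an estimated correlation). In NP3 neurons Atf3 was at 1.93 ± 0.20 and Stmn4 at −4.04, and the injury list did not pass (5 higher and 7 lower, adjusted p = 0.945). The injury list did not pass in TRPM8 (adjusted p = 0.0743), NF (adjusted p = 0.0769), NP1 (adjusted p = 0.108) or NP2 (adjusted p = 0.729). Myelinating Schwann markers were at 1752 and 1680 CPM in TH neurons against at most 588 in every other named class, and what this adds to the TH values was not tested. Satellite glia markers were at 4235 and 4045 CPM in TRPM8 neurons and at 1628 and 1144 in PEP-C. Fibroblast markers were at 682 and 239.7 CPM in PEP-C, above every other named neuron class in both libraries, and at 3710 and 3498 in its cluster of 27 cells led by Dcn. Fos and Atf3 were higher in replicate 2 than in replicate 1 in every class. Over the 3 lists and 8 classes, 191 of 344 gene and class pairs were called.

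**Figure D4:**
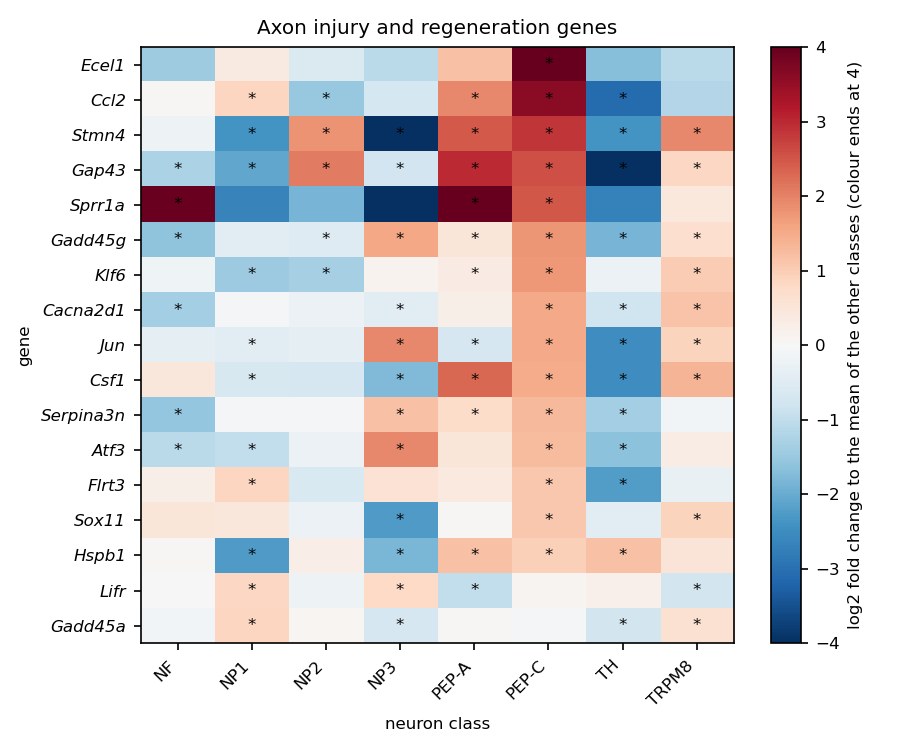
Log2 difference of each neuron class from the mean of the other classes for axon injury and regeneration genes (colour scale ends at 4), with a star at an adjusted p under 0.05. In PEP-C, 15 of 17 injury genes were higher, with Gap43 at 2.56 and Ccl2 at 3.61.

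Ligands of itch and pain were located by comparing each broad class with the mean of the others. Macrophages were higher in a set of inflammatory genes, with the chemokine Ccl3 at 881 and 3209 CPM in replicates 1 and 2 (log2 8.53 ± 0.28, SE, n = 2 libraries), Cxcl2 at 952 and 4914 (8.44 ± 0.34), Ccl4 at 1758 and 5310 (8.18 ± 0.33) and Tnf at 51.2 and 304 (8.72 ± 0.45). Macrophages also had Ltc4s, the enzyme that makes leukotriene C4, at 183 and 200 CPM (10.2 ± 0.34), while its upstream enzyme Alox5 was highest in fold in neutrophils at 87.3 and 96.9 CPM (10.1 ± 0.54). Fibroblasts were higher in the alarmin Il33, at 112 and 116 CPM (8.32 ± 0.24), and in Ptges, which makes prostaglandin E2, at 137 and 119 CPM (5.41 ± 0.24). Endothelial cells were higher in the endothelin gene Edn1, at 132 and 85.1 CPM (7.90 ± 0.39), and in Cxcl12 at 3029 and 1316 CPM (7.48 ± 0.24).

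Neutrophils were also higher in Osm, the ligand of Osmr, at 164 and 84.1 CPM (8.55 ± 0.50), and in Il1b at 1464 and 1050 CPM (7.81 ± 0.30). The T or NK cluster had Il1b at 2154 and 1728 CPM (8.09 ± 0.28), beside its macrophage markers. Mural cells were higher in Il34 (4.75 ± 0.22) and in Il6, at 30.4 and 445 CPM (5.13 ± 0.37). Fibroblasts had Cxcl1 at 224 and 1326 CPM (5.10 ± 0.31). Neurons were higher in the growth factor Bdnf, at 144 and 212 CPM (2.79 ± 0.13). Satellite glia were higher in Ptges (3.62 ± 0.26) and Il18 (2.37 ± 0.22). Of the mediators, 26 were tested and 24 reached 20 CPM in a class in both libraries, and 69 of 338 gene and class pairs were higher at that level. The mediator list as a whole was lower in NP2 and NP3 than in the peptidergic classes (1 of 15 higher and 7 lower, 9 adjusted over the list alone; adjusted p = 0.00509, and adjusted p = 0.0986 with an estimated correlation). Levels of Ccl3, Cxcl2, Ccl4, Tnf, Il6 and Cxcl1 differed by over 1.5 times between the libraries, with the higher value in replicate 2, while Cxcl12, Edn1 and Osm were higher in replicate 1.

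**Figure D5:**
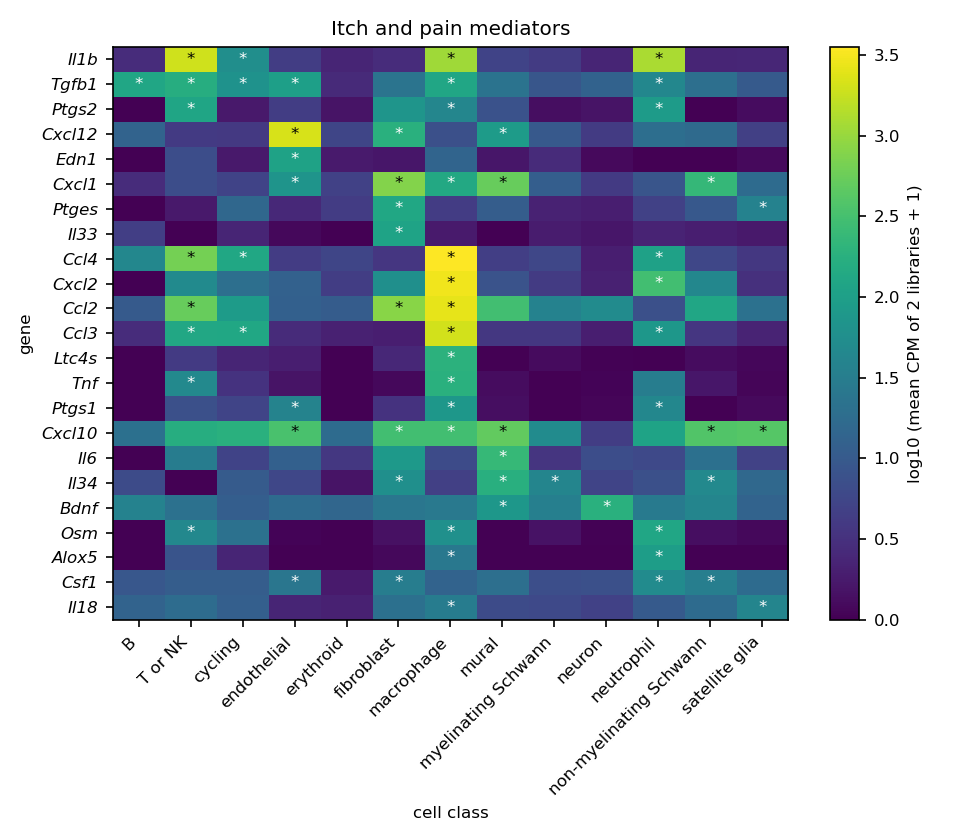
Level of itch and pain mediators by broad class as log10 of mean CPM + 1, with a star where the class was higher at an adjusted p under 0.05 and at least 20 CPM in both libraries. Chemokines such as Ccl3 and Cxcl2 were starred in macrophages and Il33 in fibroblasts.

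The spread between the libraries was measured within each class across genes above 10 CPM, which are not independent replicates. Pearson's r of log2 CPM ran from 0.955 in TRPM8 to 0.985 in NP1 among neuron classes, and from 0.744 in B cells to 0.985 in all named neurons together among broad classes. In NP1, 64 of 7435 genes (0.86%) differed by over 2-fold between the libraries, and in TRPM8 neurons 326 of 8547 (3.81%). In B cells, with 54 and 86 cells, 2540 of 8582 genes (29.6%) did, and in erythroid cells 2134 of 3718 (57.4%). B cells held only 157789 and 277093 UMIs, against 21516386 and 12111171 in NP1, so counting error enters their value. Erythroid markers took 845911 and 681464 CPM in erythroid cells, which shifts the CPM of all other genes between the libraries. These percentages thus also reflect depth and composition. Satellite glia had 231 of 8391 (2.75%) and macrophages 813 of 8412 (9.66%).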

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

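The interval on the channel ratio was chosen after the result was seen.

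Droplets of low depth that were left out of every comparison held neuronal transcripts. In replicate 1, neuron markers took 1.72% of UMIs in 1282 such droplets, against 0.146% in satellite glia and 1.70% in named neurons, and in replicate 2 they took 1.46% in 1999 droplets, against 0.213% and 1.75%. They were of a pair of kinds, led by A-fibre genes such as Nefh, Scn1a and Asic3 (1101 droplets in replicate 1 and 355 in replicate 2) or by C-fibre genes such as Scg2, Scn11a and Gal (181 and 1644).

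Free RNA of the whole library would give both kinds a like ratio of A-fibre to C-fibre channel UMIs. That ratio was 3.51 times higher in the A-fibre kind in replicate 1 (95% interval 1.91 to 6.00) and 4.49 times in replicate 2 (3.26 to 6.50). The ratios were 23.3 and 13.7 in the A-fibre kind, 6.62 and 3.05 in the C-fibre kind and 28.2 and 17.9 in satellite glia, so the widest differences were 4.25 and 5.88, where free RNA needed under 2. The C-fibre side held only 3 genes, with 29 UMIs in the C-fibre kind of replicate 1. In that library satellite glia had 6309 A-fibre channel UMIs of 21449301, and named neurons 17951 of 59759968. Neuron markers stood at 1456.4 and 17023.6 CPM, so the A-fibre channel UMIs of glia did not follow their neuronal RNA. The glial ratio may therefore not be that of free RNA. Excluding free RNA needed a ratio above 4, or an interval wholly above 2, in both libraries, so it cannot be told apart from another origin. Fragments of neurons without nuclei would have little nuclear RNA such as Malat1 and Meg3, which stood at 0.160 of the level of named neurons in the A-fibre kind of replicate 1, at 1.10 in that of replicate 2, and at 1.89 and 2.17 in the C-fibre kind. Since satellite glia hold 39549 and 37458 CPM of such RNA against 8794 and 3689 in named neurons, glial RNA could supply some of it. Satellite glia markers stood at 30161 and 15765 CPM in the C-fibre kind and at 4169 and 10444 in the A-fibre kind. In satellite glia they stood at 118893 and 106468. How much of the nuclear RNA this supplies was not tested, and fragments stay open. No biological explanation was tested, since the series has 1 group.

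In neuron cluster 22, unnamed and with 58 cells in replicate 2, Sprr1a, a gene induced by axon injury, was found in 13.8% of cells (8 of 58, 95% interval 6.15 to 25.4), above the 5.17% that a count of 0 allows. Satellite glia had 0.957%, at a median of 6009.5 UMIs against 17798.5 in the cluster, so this background was not matched for depth. In neuron cluster 25, unnamed and with 84 cells in replicate 2, Sprr1a was found in 13.1% of cells. That was 11 of 84 (95% interval 6.72 to 22.2), above 3.57%, at a median of 6370.5 UMIs. Both clusters were chosen for passing this limit, and every other unnamed neuron cluster measured was at or below its own limit.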

How the results depend on the processing

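Alternatives with neurons of at least 10000 UMIs, another clustering seed and 20000 UMIs were chosen after the data were examined. Of 4175 repeats of 265 named gene results, 4051 counted as unchanged, 35 newly passed, 80 no longer passed and 9 reversed. The unchanged include 265 repeats without replicate 1 and 264 without replicate 2, which carry no test. There only a turn of sign in a called gene could count as a change. Genes named by fold were chosen for a like sign in both libraries, so their outcome there was fixed. A gene that did not pass counted as unchanged whatever its sign. With at least 50 cells per class, which left NP2 against PEP-C, the comparison of itch-associated with peptidergic classes reversed for Il13ra1 (−1.19), Trpv1 (−1.29), Lifr (−0.29), Stat3 (−0.36), Runx1 (−1.19), Trpv2 (−0.36), Piezo2 (0.38) and Scn8a (0.72), since NP3 and PEP-A were absent. In NP1 against NP2 and NP3, Htr2a was at −0.14 without replicate 2 and 0.29 without replicate 1. NP3 against NP2 could not be made with at least 50 cells.

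Counts at a fold of at least 1.5 were 2249 for itch-associated against peptidergic classes, 1546 for NP3 against NP2 and 1569 for NP1 against NP2 and NP3, by construction of the stricter test. In other alternatives counts stayed within 1.5 times, with 3875, 2533 and 2738 in count splitting, 4046, 2552 and 2746 without the library term, and 2482 for NP1 with at least 50 cells. Of 80 list tests over the 4 comparisons, 32 passed with the preset correlation, 0 with an estimated correlation and 57 with fry, which tests lists on their own. The NP2 and NP3 share of named neurons was 13.0% and went to 9.66% at low resolution, 11.0% with the stricter filter, 10.4% with doublets kept and 10.2% with count splitting (11.7 to 14.3 with a replicate left out), and the cause was not tested. By class, NP2 went from 8.06% to 5.17% at low resolution and PEP-A from 4.98% to 7.67% with libraries centred. Of broad classes, T or NK went from 1.09% to 0.451% and cycling cells from 0.510% to 0.891% with count splitting, and unnamed barcodes from 17.9% to 5.14% with the stricter filter, where erythroid and cycling cells had no cluster. Cells named perineurial were 1.36% with libraries centred, 0.386% at high resolution and none in the main run.

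The NP3 share with an itch receptor and Trpv1 or Trpa1, 37.6%, was 14.0% at 1000 UMIs, 82.4% at 5000, 98.4% at 20000 and 98.5% without thinning, by construction of the depth, and 30.2% with doublets kept (33.3 to 41.9 with a replicate left out), where the cause was not tested. The neuron share of 10.6% ran from 10.1 to 12.8 over clusterings. Calls over the injury, immediate early and heat shock lists together, by neuron class, ran from 176 to 197. Leaving out a replicate leaves no residual degrees of freedom, so it gives signs and no test.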

Other observations

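The tests of a handling response, of glial and fibroblast RNA and of dissociation stress, and the comparisons with donor markers for Egr3 and Myc, were chosen after the results were seen, and the one for Myc replaced an earlier one that did not decide.

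NP1 neurons held more RNA of cholesterol synthesis than the itch-associated classes, with 16 of 17 genes higher and 0 lower, 16 adjusted over the list alone (adjusted p = 1.05e-14, and adjusted p = 0.0580 with an estimated correlation). Idi1 was higher by 1.40 ± 0.12 on the log2 scale (SE, n = 2 libraries), a gene chosen after its values were seen. In the itch-associated classes 13 of 17 were lower than in the peptidergic classes, 15 adjusted over the list alone (adjusted p = 0.00195, and adjusted p = 0.333 with an estimated correlation), and satellite glia exceeded neurons in 15 of 17, 16 adjusted over the list alone (adjusted p = 0.00441, and adjusted p = 0.573 with an estimated correlation). Oxidative phosphorylation was higher in NP1 in 35 of 83 genes and lower in 0, 45 adjusted over the list alone (adjusted p = 3.09e-04, and adjusted p = 0.713 with an estimated correlation), and lower in NP3 than NP2 in 14 of 83, 11 adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.785 with an estimated correlation). Interferon response genes did not pass between the itch-associated and peptidergic classes (5 of 14 higher, 2 lower, 7 adjusted over the list alone; adjusted p = 0.215), nor did heat shock genes (3 of 9 higher, 0 lower; adjusted p = 0.448), immediate early genes (0 of 17 higher, 7 lower; adjusted p = 0.304), purinergic receptors (2 of 6 higher, 3 lower; adjusted p = 0.341, median −0.25 with the test pointing up) or MHC class II genes (0 of 5 higher, 1 lower; adjusted p = 0.826).

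Unnamed neuron clusters held 103 cells of replicate 1 and 556 of replicate 2. Cluster 22 had Gap43 at 1141 CPM, Nts at 416.5 and Sprr1a at 1064.5, the last from few cells, with a UMI in 8 of 58 in replicate 2. Cluster 27, with 33 cells of replicate 2, carried Th at 2402 CPM beside the antigen presentation gene Cd74 at 355. Cluster 25 carried S100a9 at 808 CPM, a neutrophil gene, and Acta2 at 284, a mural gene.

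Satellite glia of 2 clusters were almost only in replicate 2, against 2634 and 1495 other satellite glia. The first was led by Myc and Egr3 with Cxcl10 (57 cells in replicate 1 and 828 in replicate 2). The second was led by Cxcl10 without the others (20 and 811). The first scored 1.16 for satellite glia, with no marker of that class among its 10 leading genes. Its satellite glia markers stood at 25020 and 42262 CPM. They stood at 118893 and 106468 in the satellite glia class and at 27411 and 26946 in non-myelinating Schwann cells. The name of the first cluster is thus weakly held. In a response of every class to handling, immediate early genes would be higher in replicate 2 throughout, but their median was above 0.5 on the log2 scale in 8 of 13 classes, too few or too many to decide, with T or NK cells at −0.28 and neutrophils at −0.71, so this cannot be told apart. By the test planned beforehand, RNA from other cells could supply Egr3 and Myc, at 0.447 and 0.338 of the highest other class in both clusters together (0.758 and 0.713 in the first). The later tests argued against it. Endothelial markers stood at 0.009 of the need of Egr3. Schwann markers stood at 0.334 of their level against 0.316 in other glia. They rose by a median of 0.040 and at most 0.294 of the need of Myc (0.158 and 0.479 in the first cluster). In the first cluster alone Schwann markers stood at 0.560 of their level, so the Myc test there rests on a weakly held name. No biological explanation was tested, since the series has 1 group.

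PEP-C neurons had 15 of 17 injury genes higher than the other classes. Glial and fibroblast RNA were argued against, since at the share of their markers in PEP-C they supplied at most 0.008 and 0.006 of the excess of the median called gene in either library, and for no gene with an excess (15, or 14 in replicate 1) over 0.123. A small cluster of injured cells was argued against, since all 4 of the 4 PEP-C clusters with at least 20 cells had medians above 0.5, from 0.99 to 1.23, with 0.25 in a cluster of 18 cells, although 1 of the 4, with 27 cells led by Dcn, had no PEP-C marker among its 10 leading genes. Dissociation stress cannot be told apart, since 1 of its lists, immediate early genes, passed and heat shock genes did not, and the first did not pass with an estimated correlation (adjusted p = 0.272). A state of these neurons, or a standing difference of the class, may remain, and neither was tested, since the series has 1 group.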
